A study of Mus musculus with 6 samples.

How the data were processed

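The series holds 6 bulk RNA-seq libraries of cultured mouse aortic endothelial cells (MAEC) whose genotype label is Oct4 KO, 3 from female and 3 from male mice. Per the labels, the cells were grown untreated in serum-containing medium with heparin and endothelial growth supplement, and polyadenylated RNA was selected, fragmented and copied from random hexamer primers. The library protocol in the labels allows a strand-marking and a non-marking version and does not say which was used here, and the strand setting of the counting is not given in the sources used here, so a gene and its antisense partner cannot be told apart. Reads were aligned with HISAT2 2.0.5 to mm10 and assigned to genes with featureCounts 1.5, per the submitters' processing notes. The deposited table gives raw read counts per gene, whole numbers that the authors did not normalise, for 54532 genes in the 6 libraries, with Ensembl identifiers, symbols, coordinates and biotypes. How multi-mapping reads were counted is not given in the sources used here. Genes with close paralogs or pseudogenes (the H2 genes, Ifit3 and Ifit3b, Ces1g, Mid1 and Mid1-ps1, Gapdh, Pou5f1 and the mitochondrially encoded genes with nuclear copies) are therefore uncertain. Each of the 6 columns was matched to its sample by the library name in the labels, and the table held 0 other columns of samples and 0 rows without a gene name. Of the identifiers, 99.9% were found in GENCODE M21, and 98.3% of those had identical chromosome, start, end and strand there. A total of 103 rows repeated the symbol of an earlier row. Rows were tested apart by identifier, and in the gene lists a symbol stood for its row with the highest total count.

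Total counts per library were 19299742 to 23064738. A number of 3 counts, the upper limit that a count of 0 allows at 95%, corresponded to 0.123 to 0.154 CPM over the effective library sizes. Such limits and the counting intervals cover counting error only, since the reads carried no molecular identifiers. Where a gene had 0 counts in every library of a group, the fold is a lower bound against 3 counts per library, and with 1 to 3 counts in the group the ratio is given with its 95% counting interval. A CPM here is the usual scaled count, taken over the effective library size, which is the library size multiplied by its TMM factor (0.948 to 0.968 in the female and 1.03 to 1.06 in the male libraries), given as mean ± SD with n = 3 per sex. Libraries of the same sex differed by more than sampling noise (chi-square per degree of freedom 7.4 to 16), so no pair was treated as a single library given more than once. That does not show that they came from separate cultures or animals. Their log2 CPM correlated at 0.987 to 0.993 within a sex and 0.739 to 0.775 between the sexes, across 10812 tested genes with a mean of at least 5 CPM, which are not independent replicates. Fold changes are female over male on the log2 scale, given as estimate ± SE. The SE was taken as the size of the log2 fold change divided by the square root of the F statistic of its edgeR test. Where a sex had few counts, this SE can be smaller than the counting error and then overstates the precision.

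The comparison of the sexes was fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM, glmQLFit and glmQLFTest, sex as the only term), with two-sided p-values and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes. The directional p of fry asks whether the members moved, on balance, one way, without comparing them with other genes. Each member count is over all genes tested, and the counts adjusted over the list alone are given where they differ.

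The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except those named below. The 46 lists covered sex-linked label checks, pluripotency, endothelial and other cell types, angiogenesis, matrix, signalling, cell cycle, stress, metabolism, immune response, Hox genes and imprinted genes. The rule named Pou5f1 and the sex-linked check genes. It also named the 10 genes with the largest change in each direction among autosomal protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the sexes. Of each list discussed, it named up to 4 members with the smallest adjusted p. Other genes named in the text, among them the members behind counts of 5 or fewer and the Hox genes outside those 4, were chosen after their values were seen. Single values of 3 members of these lists are not reported or drawn here; the list tests and counts include them.

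The fit was tested on counts simulated from the real library sizes and the means over all 6 libraries, with 200 changed genes among 14814. All tested interferon response genes were shifted up in female as well and counted as changed. Of the genes changed 1.5-fold the fit recovered 53.7%, of those changed 2-fold 79.1% and of those changed 4-fold 98.5%. Of its calls 5.24% were unchanged genes. The simulated changes were far fewer than the genes called in the real data, so these shares do not give the false calls there. Alternatives were DESeq2 1.42.0, limma-voom, other scalings (DESeq2-style size factors, upper quartile, total count only), no low-count filter, a minimum of 1 CPM in 3 libraries, robust dispersions, a tested minimum fold of 1.5 (glmTreat), the replicate number as a block, protein-coding genes only, and each library left out in turn. After the data had been seen, a correction of each library for gene length and transcript GC content was added, alone and with the replicate block, because fold changes followed gene length. It used the gene length given in the deposited table. The GC content was that of the longest GENCODE M21 transcript of a gene, found for 99.9% of the tested genes. Figures and closing tests used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Wild-type cells belong to another series and are not analysed here, so the effect of the knockout itself was not tested.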

Results

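Gene expression was measured by bulk RNA-seq in cultured primary mouse aortic endothelial cells from mice carrying an endothelial-specific knockout of Oct4, the pluripotency transcription factor encoded by Pou5f1. The cells had been isolated from the aortas of female and male mice, and the stated interest of the study was the role of OCT4 in endothelial cells of each sex. There were 3 female and 3 male libraries. The labels do not say whether the 3 libraries of a sex came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Total counts were 21483163, 20621075 and 20404758 in the female libraries and 20291328, 19299742 and 23064738 in the male libraries. Spp1, which encodes the secreted phosphoprotein osteopontin, took 5.26% ± 0.22 of the counts in the female and 2.24% ± 0.20 in the male libraries (SD, n = 3 each). Mitochondrially encoded genes took 2.29% ± 0.26 and 2.40% ± 0.30. Genes annotated as ribosomal RNA took 0.13%, 0.116% and 0.141% in the female libraries and 0.074%, 0.07% and 0.082% in the male libraries. What that difference reflects was not tested. With wild-type cells not analysed here, the comparison is between the sexes within the knockout genotype.

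Pou5f1 (ENSMUSG00000024406, mm10 chromosome 17, 35506018 to 35510772) had 0 counts in each of the 6 libraries, which allows at most 0.154 CPM in any of them. Without wild-type libraries this value does not separate a deleted gene from one not expressed in cultured aortic cells, so it does not check the genotype label. The sex labels were checked on sex-linked genes. Xist, the RNA that coats the inactive X chromosome, had 28171, 31900 and 21282 counts in the female libraries and 8, 0 and 5 in the male libraries. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 counts in every female library. In the male libraries they stood at 46.7 ± 8.73, 32.4 ± 6.37, 52.8 ± 5.84 and 15.7 ± 5.64 CPM (SD, n = 3), at least 311-, 216-, 352- and 105-fold higher than in the female libraries. Zfy1, Zfy2 and Usp9y had 0 counts in all 6 libraries. Of 15 X-linked genes listed as expressed from the inactive X, 7 were higher in female cells (Xist, Kdm6a, Eif2s3x, Mid1, 5530601H04Rik, Ddx3x and Kdm5c), 3 were lower (Bgn, Utp14a and Car5b) and 5 were not called. Kdm6a, a histone demethylase gene, was at 47.7 ± 2.61 CPM in female and 14.1 ± 1.26 in male cells (log2 fold change 1.76 ± 0.11, edgeR adjusted p = 5.79e-10). The call of 5530601H04Rik was lost with the length and GC correction (log2 0.73 before and 0.23 after, adjusted p = 0.247), while Ftx (log2 -0.66, adjusted p = 0.000712) and Tmem29 (-0.46, 0.033) were then called lower. Ftx was also called lower with upper quartile scaling (adjusted p = 0.0238), with total counts (0.016), without female replicate 3 (0.0397) and without male replicate 2 (0.0343).

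Female and male Oct4 KO cells differed in most of the genes they expressed, and the largest differences were in genes read only or almost only in cells of one sex. Pax1 (mm10 chromosome 2, 147361925 to 147393295), a paired-box transcription factor of embryonic patterning, was at 75.7 ± 7.39 CPM in female cells with 0 counts in every male library, at least 544-fold higher. Gata4 (chromosome 14, 63198922 to 63271692), a zinc-finger transcription factor of heart and mesoderm development, was at 68.4 ± 4.20 CPM in male cells with 0 counts in every female library, at least 455-fold higher in male. Hoxc8 (chromosome 15, 102990607 to 102994111), a homeobox gene of trunk identity, was at 42.9 ± 2.36 CPM in female cells with 0 counts in every male library, at least 308-fold higher. Female cells also carried more Spp1 RNA, the most abundant message by mean CPM in each sex, at 54780 ± 2029 against 21590 ± 2008 CPM (log2 fold change 1.34 ± 0.08, edgeR adjusted p = 3.75e-10).

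Of 14814 genes tested, 8993 were called (60.7%), 4580 higher and 4413 lower in female cells. The calls were not confined to the sex chromosomes, since 8660 of 14301 autosomal genes were called (60.6%), with 4374 higher and 4286 lower. On the X chromosome 194 of 472 tested genes were higher and 113 lower in female cells. Of 8 tested genes placed on the Y chromosome, Ddx3y, Kdm5d, Eif2s3y, Uty and Gm29650 were lower in female cells, where each was at 0 CPM. Mid1-ps1 and Gm21860 were higher, and both lie within 90753057 to 90763485 of the Y chromosome. Gm47283 (90784738 to 90816464) was not called, at 20.4 ± 12.8 CPM in female and 22.1 ± 1.47 in male cells. Mid1-ps1 is a pseudogene of the X-linked Mid1. Since the female libraries lacked the genes named first, reads assigned to Mid1-ps1, Gm21860 and Gm47283 need not come from a Y chromosome and are uncertain. A total of 3499 called genes differed at least 2-fold, 2036 of them higher in female cells. The CPM of the sexes did not overlap for 67.1% of the tested genes, where chance gives 10%. Without any normalisation beyond the total count, the median of all genes shifted by -0.12 on the log2 scale and the split became 3956 higher and 5294 lower.

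The 10 largest autosomal differences toward female cells were Pax1, Cadm2, Edil3, Hoxc8, Slitrk6, Fbn2, Dach1, Grik2, F830016B08Rik and Cnr1, each with 0 counts in all 3 male libraries. Their female levels ran from 19.3 ± 1.61 CPM for Cnr1, the cannabinoid receptor 1 gene (at least 139-fold higher), to the 75.7 CPM of Pax1. Edil3, which encodes an integrin-binding matrix protein made by endothelial cells, was at 45.1 ± 1.61 CPM (at least 325-fold). Fbn2, the gene of the microfibril protein fibrillin-2, was at 39.0 ± 9.11 CPM (at least 280-fold). The 10 largest toward male cells were Gata4, Gdf10, Hpca, Tcf21, Pcsk6, Clca3a2, Eef1a2, Tbx5, Fndc1 and Ces1g. Tcf21 and Tbx5, transcription factors of cardiac and other mesoderm, were at 21.2 ± 0.864 and 11.1 ± 1.15 CPM in male cells with 0 counts in every female library, at least 141- and 73.6-fold higher in male. Hpca, Pcsk6, Fndc1 and Ces1g had 1 to 3 counts in the female libraries together. The male over female ratio of Hpca was 5290 (95% counting interval 950 to 209000) and that of Fndc1 was 2120 (587 to 17500). Ces1g shares sequence with other carboxylesterase genes, so its level is uncertain.

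**Figure D1:**
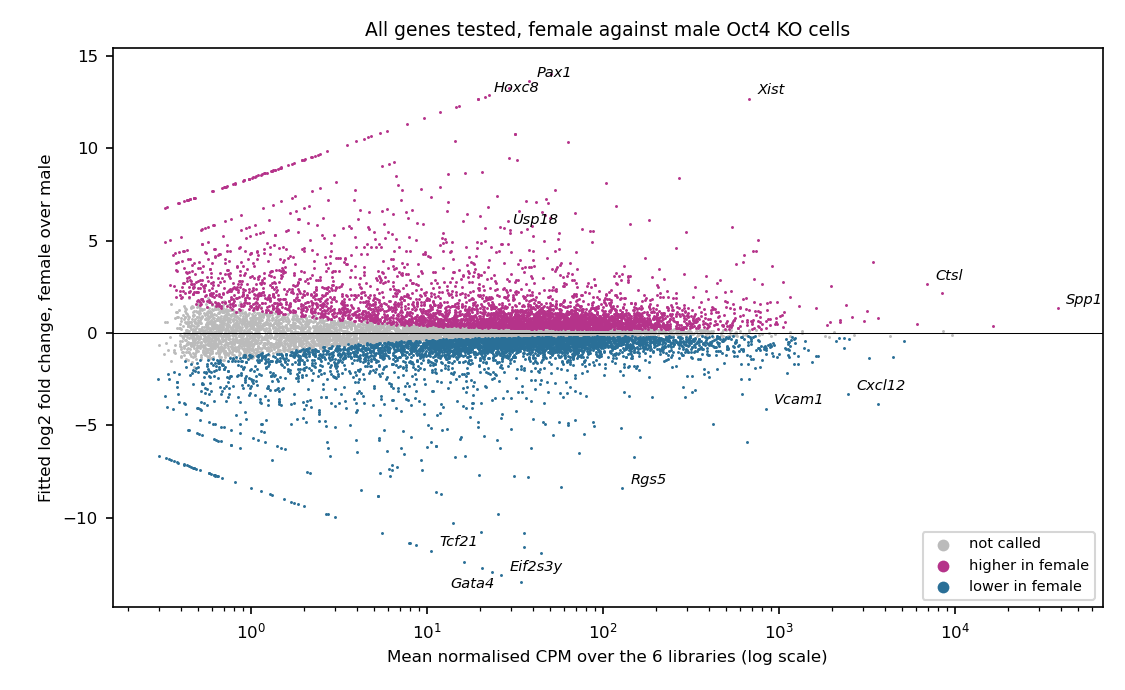
Mean normalised CPM over the 6 libraries (x, log scale) against the fitted log2 fold change of female over male (y) for the 14814 tested genes; each point is a gene, coloured where called at an adjusted p under 0.05. The 4580 genes above 0 and the 4413 below it spread over the whole range of levels, and the diagonal streaks at the edges are genes with 0 counts in every library of a sex, whose fitted fold changes depend on the prior count.

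Cells of both sexes carried little RNA of the classical endothelial genes and much RNA of fibroblast and mesenchymal genes. Of 36 pan-endothelial genes, 23 were under 1 CPM in all 6 libraries, and 6 of these, Emcn, Cldn5, Robo4, Sox17, Tal1 and Gpihbp1, had 0 counts in all 6. The median over the list was 0.214 CPM in female and 0.184 in male cells. Cdh5, which encodes the endothelial junction protein VE-cadherin, had 0, 4 and 0 counts in the female and 2, 0 and 3 in the male libraries. Pecam1, the CD31 gene, was at 0.723 ± 0.292 CPM in female and 1.57 ± 0.351 in male cells. Kdr, the main VEGF receptor gene, had 6, 16 and 6 counts in the female libraries and 0 in each male library. Only Eng, Calcrl, Flt1 and Cd34 reached 10 CPM in every library. By contrast, 18 of 26 fibroblast and mesenchymal genes reached 10 CPM in all 6 libraries. Col1a1, a fibrillar collagen gene, was at 1176 ± 84.5 and 1143 ± 79.9 CPM in female and male cells, and Pdgfra, a receptor gene of mesenchymal cells, was at 846 ± 53.7 and 531 ± 23.9.

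The low-count filter left 12 pan-endothelial genes to test: 4 were higher in female cells (Cd34, Flt1, Sox7 and Clec14a), 4 lower (Eng, Fli1, Plvap and Pecam1) and 4 not called. Adjusted over the list alone, 5 were higher and 5 lower. Eng, a TGF-beta co-receptor gene, was at 92.2 ± 8.93 CPM in female and 253 ± 31.9 in male cells (log2 -1.46 ± 0.10), and Flt1, VEGF receptor 1, at 57.7 ± 8.13 and 27.6 ± 3.56 (log2 1.06 ± 0.12). The list as a whole was not called (camera adjusted p = 0.825). Of 25 tested fibroblast genes 14 were higher and 8 lower in female cells, with a median log2 fold change of 0.67 (camera adjusted p = 0.00371, adjusted p = 0.416 with an estimated correlation). Limma-voom did not call this list (adjusted p = 0.0883). The small proteoglycan genes Dcn (6375 ± 449 against 442 ± 58.7 CPM) and Lum (1686 ± 34.2 against 138 ± 10.4) were among the higher, as were Col6a3 (log2 4.20 ± 0.09) and Pi16 (6.12 ± 0.18). Tcf21, Fbln1 and Mfap5 were among the lower.

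Markers of other cell types divided between the sexes. Of 12 smooth muscle genes Synpo2, Tpm1 and Itga8 were higher, Acta2, Smtn, Lmod1 and Myl9 lower and 5 not called, and Acta2, the smooth muscle actin gene, stood at only 3.71 ± 0.696 CPM in female and 23.3 ± 1.75 in male cells (camera adjusted p of the list = 0.643). Of 11 pericyte genes Kcnj8, Abcc9, Cspg4, Notch3 and Anpep were higher and Rgs5, Pdgfrb, Cox4i2 and Ndufa4l2 lower (camera adjusted p = 0.96). Rgs5, a regulator of G-protein signalling, was at 0.756 ± 0.456 CPM in female and 256 ± 10.2 in male cells, while Cspg4, the NG2 proteoglycan gene, was at 109 ± 12.7 and 3.19 ± 0.233. Ptprc, the CD45 gene of leukocytes, had 0 counts in all 6 libraries, and 19 of 24 macrophage and leukocyte genes were under 1 CPM in all. Of the 4 that could be tested Cd14 and Cd68 were higher, Lyz2 was lower and Csf1r was not called (adjusted over the list alone it was lower, as it was without male replicate 2, adjusted p = 0.049, with upper quartile scaling, 0.0432, with total counts, 0.0365, and among protein-coding genes only, 0.0478). Of 4 testable mesothelial and epithelial genes Bnc1 was higher and Cldn15 and Krt19 lower. Of 7 adipocyte genes Cd36 and Plin4 were higher and Pparg, Retn, Fabp4 and Lipe lower (camera adjusted p = 0.232). Of 18 pluripotency genes 14 were under 1 CPM in all libraries. Among the other 4 Tbx3 was higher (156 ± 8.04 against 32.9 ± 0.935 CPM) and Klf2, Klf4 and Myc were lower. Myc was at 85.3 ± 3.04 and 98.1 ± 6.03 CPM (log2 -0.20 ± 0.08, edgeR adjusted p = 0.0408). Its call did not hold without female replicate 1 (adjusted p = 0.135), female replicate 2 (0.0863), male replicate 1 (0.16) or male replicate 2 (0.0565), without the low-count filter (0.0733) or with the replicate block (0.0872), nor with the length and GC correction, where its fold change was 0.02 (adjusted p = 0.803).

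**Figure D2:**
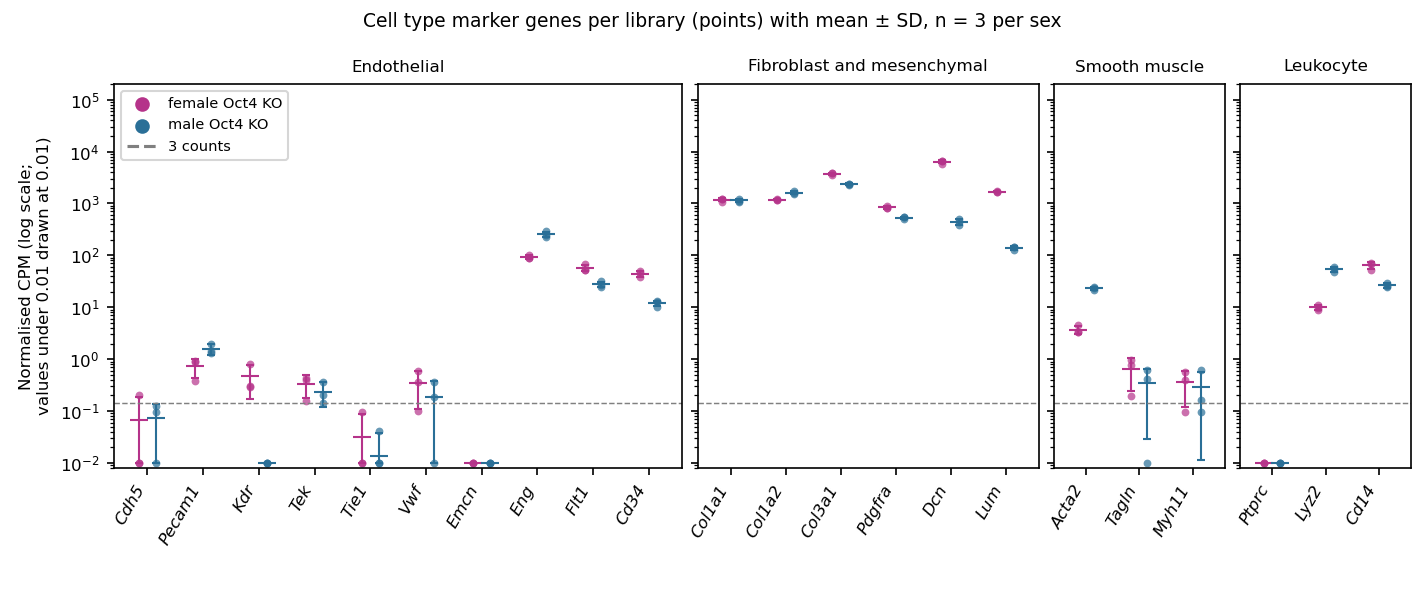
Normalised CPM (log scale) of endothelial, fibroblast, smooth muscle and leukocyte marker genes in each library; points are libraries, bars are mean ± SD (n = 3 per sex), the dashed line is the mean level of 3 counts and values under 0.01 are drawn at 0.01. The means of Cdh5, Emcn and Tie1 lie under the line in both sexes while Col1a1, at 1176 and 1143 CPM, lies far above it.

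Genes of positional identity differed between the sexes. All 5 tested genes of the HoxC cluster on chromosome 15 were read in female cells and nearly absent from male cells. Hoxc6 was at 64.6 ± 5.37 CPM against 3, 0 and 3 counts in the male libraries (log2 9.37, resting on few male counts). Hoxc4 was at 16.3 ± 0.300 CPM against 1, 7 and 2 counts. Hoxc8, Hoxc5 and Hoxc9 had 0 counts in every male library. The annotated span of Hoxc5 (102967443 to 103017429) contains Hoxc6, Hoxc8 and Hoxc9, so the split of reads among these genes is uncertain. Of 22 Hox genes tested 16 were higher in female cells, 4 were lower, among them Hoxa3, Hoxa4 and Hoxa10, and 2 were not called (5 lower adjusted over the list alone), with a median log2 fold change of 1.41 (camera adjusted p = 3.39e-07, adjusted p = 0.141 with an estimated correlation). With zero-count genes set to their bounds the median was also 1.41. Hoxb9 was at 23.7 ± 1.22 CPM in female cells against 6, 0 and 0 counts in male cells. Hoxa10 went the other way, at 5.60 ± 1.27 CPM in male cells against 3 counts in the female libraries together, a male over female ratio of 111 (95% counting interval 37.6 to 540). Of 21 imprinted genes 14 were higher and Grb10 and Ndn lower (3 lower adjusted over the list alone, 4 lower with upper quartile scaling, total counts or the length and GC correction), with a median of 1.64 (camera adjusted p = 1.01e-05, adjusted p = 0.141 with an estimated correlation). Dlk1, a paternally expressed Notch-family ligand gene, was at 279 ± 45.4 against 4.78 ± 1.95 CPM, Rasgrf1 at 149 ± 33.3 against 3.01 ± 0.574, Peg10 at 247 ± 40.9 against 29.1 ± 3.14 and the maternally expressed RNA Meg3 at 333 ± 18.3 against 86.1 ± 5.80.

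**Figure D3:**
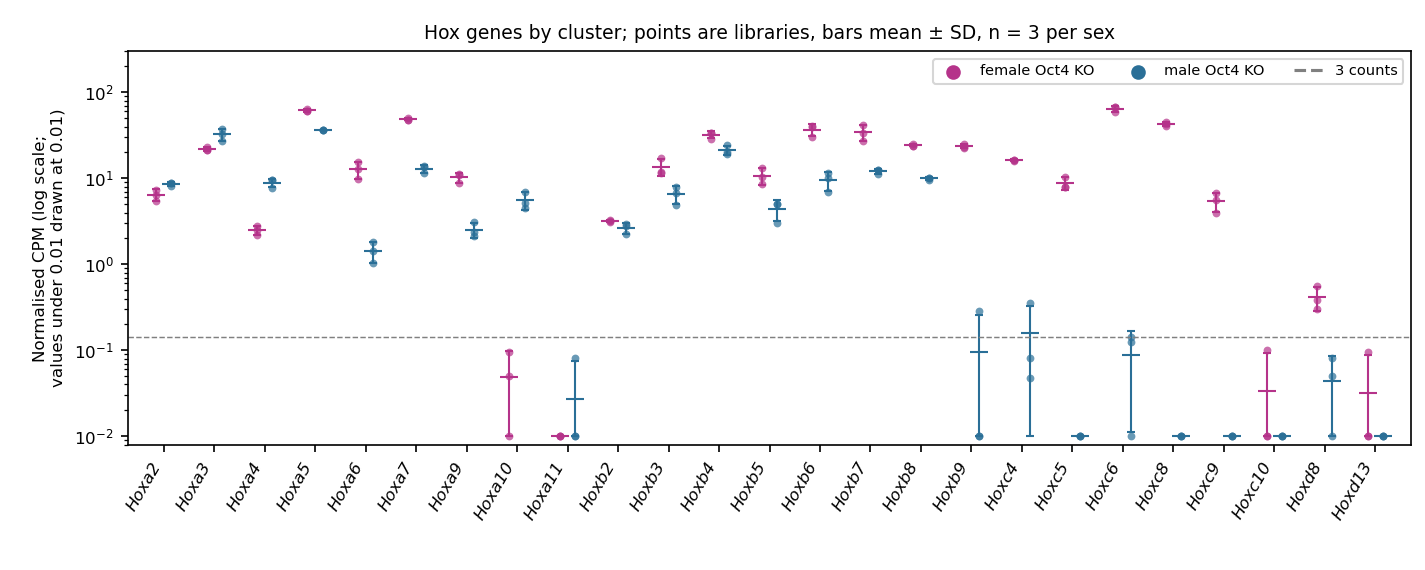
Normalised CPM (log scale) of 25 Hox genes of the list, each with at least 1 count, ordered by cluster; points are libraries, bars are mean ± SD (n = 3 per sex), the dashed line is the mean level of 3 counts and values under 0.01 are drawn at 0.01. HoxA and HoxB genes are mostly read in both sexes, whereas Hoxc4 to Hoxc9 and Hoxb9 are read in female cells, with at most 10 counts in the male libraries together.

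Interferon-stimulated genes were almost uniformly higher in female cells. Of 42 tested members 41 were higher and Ifi27l2a was lower, with a median log2 fold change of 3.22 (camera adjusted p = 6.82e-26). That call was lost when the correlation between the genes was estimated (adjusted p = 0.213 with an estimated correlation, which was 0.519). Usp18, a negative regulator of interferon signalling, was at 53.9 ± 8.57 CPM in female and 1.05 ± 0.644 in male cells (log2 5.68 ± 0.25, edgeR adjusted p = 4.36e-12). Ifit1, which encodes an RNA-binding antiviral protein, was at 56.1 ± 12.3 and 2.01 ± 0.488 (log2 4.80 ± 0.20). The class I histocompatibility genes H2-D1 (340 ± 22.5 against 41.0 ± 1.24 CPM) and H2-K1 (263 ± 22.2 against 52.8 ± 1.42) were higher, although reads of H2 genes can be shared with their paralogs. In the overlapping antigen presentation list 12 of 17 genes were higher, H2-T23, Tap2 and H2-Eb1 lower and 2 not called, with a median of 1.54 (camera adjusted p = 1.01e-05, adjusted p = 0.213 with an estimated correlation). Nlrc5, the transactivator of class I genes, was at 25.7 ± 3.59 against 0.255 ± 0.0925 CPM.

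Cell cycle and oxidative phosphorylation genes were lower in female cells. Of 30 S-phase genes 25 were lower, E2f8 was higher and 4 were not called, with a median of -1.03 (camera adjusted p = 8.98e-06, adjusted p = 0.056 with an estimated correlation). Mcm3 and Mcm5, subunits of the replicative helicase, were at 15.2 ± 2.79 against 56.4 ± 2.21 and 7.60 ± 0.726 against 32.6 ± 4.33 CPM. Of 36 G2 and M phase genes 30 were lower and 6 not called, with a median of -0.92 (camera adjusted p = 6.88e-06, adjusted p = 0.056 with an estimated correlation). Cdk1, the mitotic kinase gene, was at 21.7 ± 1.86 against 54.4 ± 2.79 CPM and Nuf2, a kinetochore gene, at 4.92 ± 0.458 against 22.4 ± 1.03. Of 72 nuclear oxidative phosphorylation genes 65 were lower and 7 not called (66 lower adjusted over the list alone), with a median of -0.69 (camera adjusted p = 2.95e-08, adjusted p = 0.416 with an estimated correlation). Ndufs8, a subunit of respiratory complex I, was at 23.7 ± 2.70 against 65.9 ± 6.82 CPM (log2 -1.47 ± 0.11).

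Fold changes followed gene length across the 10812 tested genes with a mean of at least 5 CPM. From the shortest to the longest of 5 equal groups of genes the median log2 fold change was -0.40, -0.19, 0, 0.16 and 0.39 (Spearman rho 0.38 across genes, which are not independent replicates). Per library, the slope of a gene's log2 CPM on log2 gene length, against the mean of the libraries, was 0.071 to 0.185 in the female and -0.159 to -0.103 in the male libraries. A smaller trend also lay between libraries of the same sex, shown here for the library with the steepest slope in each sex. From the shortest to the longest genes, the median of female replicate 2 minus the other female libraries went from -0.12 to 0.12. That of male replicate 2 minus the other male libraries went from 0.06 to -0.07. The trend between the sexes may be technical, which was not tested. After the length and GC correction rho was 0.04. Oxidative phosphorylation genes then had a median of -0.43 with 51 lower and 2 higher, S-phase genes -1.30 with 28 lower, and G2 and M phase genes -0.99 with 35 lower. The camera adjusted p of the oxidative phosphorylation list was then 0.000234, and 0.395 with an estimated correlation.

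Of the remaining stress and metabolic lists only that of oxidative stress was called by camera at the preset correlation, with most of its genes lower in female cells. Of 31 oxidative stress genes 20 were lower (21 adjusted over the list alone), Gclc, Srxn1, Slc7a11, Prdx6 and Cybb were higher (3 higher with total counts) and 6 were not called, with a median of -0.73 (camera adjusted p = 7.84e-05, adjusted p = 0.199 with an estimated correlation). Gpx3, the secreted glutathione peroxidase gene, was at 6.84 against 247 CPM (log2 -5.17 ± 0.15), whereas Slc7a11, the cystine transporter gene, was at 63.0 ± 10.4 against 9.90 ± 1.65. Of 13 mitochondrially encoded genes 12 were tested: mt-Nd5 was higher, mt-Nd3, mt-Nd6, mt-Co2 and mt-Co3 were lower (3 adjusted over the list alone) and 7 were not called (camera adjusted p = 0.705). The counts depended on the processing: 2 were lower without female replicate 1 or male replicate 1, 7 were lower without male replicate 3 or with total counts, and with the length and GC correction 3 were higher and 2 lower. The call of mt-Co2 did not hold without female replicate 1 (adjusted p = 0.0675) or male replicate 1 (0.0813), nor with the length and GC correction (0.0924). Mt-Co2 and mt-Co3, at 18.7 to 32.9 CPM against 8176 to 8947 for mt-Co1, are uncertain because nuclear copies can share their reads. Of 25 p53 and senescence genes 15 were lower and 5 higher, the latter Igfbp5, Igfbp3, Pmaip1, Trp53inp1 and Sesn2 (camera adjusted p = 0.113). Of 20 glycolysis genes 10 were lower (11 adjusted over the list alone) and Pfkp, Eno2, Slc16a3 and Slc16a1 higher (0.705). Of 25 heme and iron genes 13 were lower and 6 higher (0.232); Fth1, ferritin heavy chain, was at 2600 ± 110 against 6310 ± 345 CPM. Of 27 unfolded protein and integrated stress response genes 10 were higher and 12 lower (13 adjusted over the list alone, camera adjusted p = 0.779), with Manf and Sdf2l1 among the lower. Of 25 cholesterol synthesis genes 15 were higher and Sc5d and Ebp lower (camera adjusted p = 0.111), and limma-voom called this list and the p53 list (adjusted p = 0.0112 and 0.0381), while in the edgeR fit with an estimated correlation neither was called (0.299 and 0.373). Of 30 fatty acid genes 15 were higher and 9 lower (0.779), with Scd1 higher and Angptl4 lower. Of 25 ABC transporter genes 13 were higher (14 adjusted over the list alone) and 6 lower (0.723), with the cholesterol exporter gene Abca1 at 158 ± 15.2 against 20.7 ± 4.10 CPM.

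Angiogenic genes, the subject of the series title, went both ways. Vegfa, the main endothelial growth factor gene, was at 1155 ± 80.8 CPM in female and 397 ± 46.5 in male cells (log2 1.54 ± 0.09, edgeR adjusted p = 2.74e-10). Of 50 angiogenic factor and receptor genes 20 were higher (21 adjusted over the list alone), 17 lower and 13 not called (camera adjusted p = 0.705). Nrp2, a co-receptor of VEGF-C and semaphorins, was at 173 ± 11.4 against 3.77 ± 0.571 CPM, Angptl2 at 685 ± 24.8 against 80.1 ± 3.81 and Bmp2 at 245 ± 17.1 against 30.5 ± 3.72. Ctgf, a matricellular growth factor gene, went the other way at 6.47 ± 2.40 against 319 ± 0.623 CPM. Of 25 angiogenesis inhibitor genes 12 were higher, among them Adamts1 and Dcn, and 11 lower, among them Rgs5 and Spry1 (camera adjusted p = 0.898). Of 18 tip cell genes 8 were higher and 6 lower (camera adjusted p = 0.705). Esm1, a tip cell proteoglycan gene, was at 21.5 ± 6.01 against 1295 ± 107 CPM, and Igfbp3 at 94.8 ± 13.9 against 8.49 ± 0.625.

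Venous and lymphatic genes were higher and arterial genes divided. Of 8 tested venous and lymphatic genes 7 were higher in female cells (Nrp2, Fgl2, Pdpn, Flt4, Thy1, Nr2f2 and Ephb4) and Sema3d was lower, with a median of 1.23 (camera adjusted p = 5.82e-07, adjusted p = 0.056 with an estimated correlation). The median was 0.71 without female replicate 3, 0.86 without female replicate 2, 1.73 without male replicate 1 and 0.75 without the low-count filter. Of that list 10 of 18 genes were under 1 CPM in all libraries, and Thy1 and Pdpn are also genes of fibroblasts. Of 12 arterial genes Cxcr4, Gja5, Mecom and Efnb2 were higher and 6 lower, with a median of -0.17 (camera adjusted p = 0.00146, adjusted p = 0.141 with an estimated correlation). Limma-voom did not call this list (adjusted p = 0.278). Its median was -0.27 without female replicate 1, -0.29 with total counts, -0.32 without the low-count filter and -0.50 with the length and GC correction, where 7 genes were lower. Cxcl12, a chemokine gene also expressed by mesenchymal cells, was at 446 ± 30.8 against 4481 ± 240 CPM, Unc5b, a netrin receptor, at 47.9 ± 3.90 against 538 ± 29.9 and Notch4 at 4.32 ± 0.559 against 49.9 ± 5.49. Of 15 Notch pathway genes 7 were higher and Notch4 and Hes1 lower (4 lower with the length and GC correction), with 6 not called (camera adjusted p = 0.442). Of 43 guidance genes 26 were higher, 12 lower and 5 not called, with a median of 0.72 (camera adjusted p = 0.00128, adjusted p = 0.373 with an estimated correlation). The semaphorin gene Sema7a was at 1406 ± 89.5 against 64.7 ± 1.76 CPM and the netrin gene Ntn1 at 329 ± 17.7 against 19.8 ± 2.38.

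Most genes of the list of matrix proteases and their inhibitors were higher in female cells, while structural matrix genes went both ways. Of 29 proteases and inhibitors 18 were higher, 6 lower (among them Timp3, Timp1, Adamts9, Serpine2 and Plat) and 5 not called, with a median of 0.93 (camera adjusted p = 2.43e-07, adjusted p = 0.056 with an estimated correlation). Timp1, Timp3 and Serpine2 encode protease inhibitors. The cathepsin genes Ctsl (11970 ± 550 against 1920 ± 66.6 CPM) and Ctsk (1058 ± 64.5 against 78.5 ± 4.30) and the gelatinase gene Mmp2 (3365 ± 30.8 against 587 ± 35.2) were among the higher. Of 20 basement membrane genes 8 were higher and 9 lower (camera adjusted p = 0.303), with Agrn higher and Col15a1 and Col4a5 lower. Of 31 elastic and fibrillar matrix genes 13 were higher, among them Tnc and Col12a1, and 12 lower (0.252). Of 32 integrin and adhesion genes 19 were higher, among them Itga2 and Itga6, and 9 lower (camera adjusted p = 0.0894). Without female replicate 3 that list was called (adjusted p = 0.0491); with all libraries and an estimated correlation it was not (0.373). Of 22 genes of the endothelial-to-mesenchymal transition 12 were higher and 7 lower, with Tgfbr3 higher and Cdh2 lower (camera adjusted p = 0.779). TGF-beta and BMP genes divided into 14 higher and 15 lower of 37 (15 and 16 adjusted over the list alone, camera adjusted p = 0.833), Wnt genes into 14 and 11 of 33 (15 and 11, 0.232) and Hippo/YAP target genes into 9 and 8 of 24 (0.172). Wnt5a was at 102 ± 5.11 against 8.37 ± 1.79 CPM, and the BMP antagonist gene Bmper at 8.92 ± 1.45 against 73.1 ± 3.52. The YAP targets Ctgf, Ankrd1 and Amotl2 were lower, with log2 fold changes of -5.63 ± 0.16, -5.62 ± 0.20 and -2.45 ± 0.11, and Igfbp3 was higher.

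Vascular tone, inflammatory and remaining lists were mixed. Of 29 coagulation and vascular tone genes 12 were higher and 13 lower (14 adjusted over the list alone, camera adjusted p = 0.723). Thbd, the thrombomodulin gene, was at 1390 ± 31.8 against 219 ± 16.9 CPM and Ednrb, an endothelin receptor gene, at 103 ± 10.7 against 4.75 ± 0.934. Agtr2, the X-linked angiotensin type 2 receptor gene, was at 101 ± 18.8 CPM in female cells with 0 counts in every male library, at least 728-fold higher. Of 29 inflammatory and leukocyte adhesion genes 13 were higher (14 adjusted over the list alone) and 10 lower (camera adjusted p = 0.779). Vcam1, the leukocyte adhesion molecule gene, was at 93.1 ± 4.79 against 1594 ± 79.9 CPM, and the cytokine gene Lif at 770 ± 68.3 against 119 ± 3.98. Of 20 immediate early genes 10 were higher and Junb, Egr2 and Hspa1b lower (camera adjusted p = 0.102), and with the length and GC correction the list was called (adjusted p = 0.00232), but not with an estimated correlation (0.299, and 0.101 with the correction). Jun and Nr4a1 were among the higher. Of 11 sex steroid genes Nrip1 and Igfbp4 were higher and 4 lower, among them Cxcl12, Hsd17b11 and Hsd17b4 (camera adjusted p = 0.317). Esr1, the estrogen receptor alpha gene, was at 0.883 ± 0.150 and 1.24 ± 0.358 CPM (log2 -0.47 ± 0.46, edgeR adjusted p = 0.388). Of 23 hypoxia genes 8 were higher (10 adjusted over the list alone) and 10 lower (camera adjusted p = 0.962), with Vegfa and Hif1a higher and Plod2 and Adm lower.

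**Figure D4:**
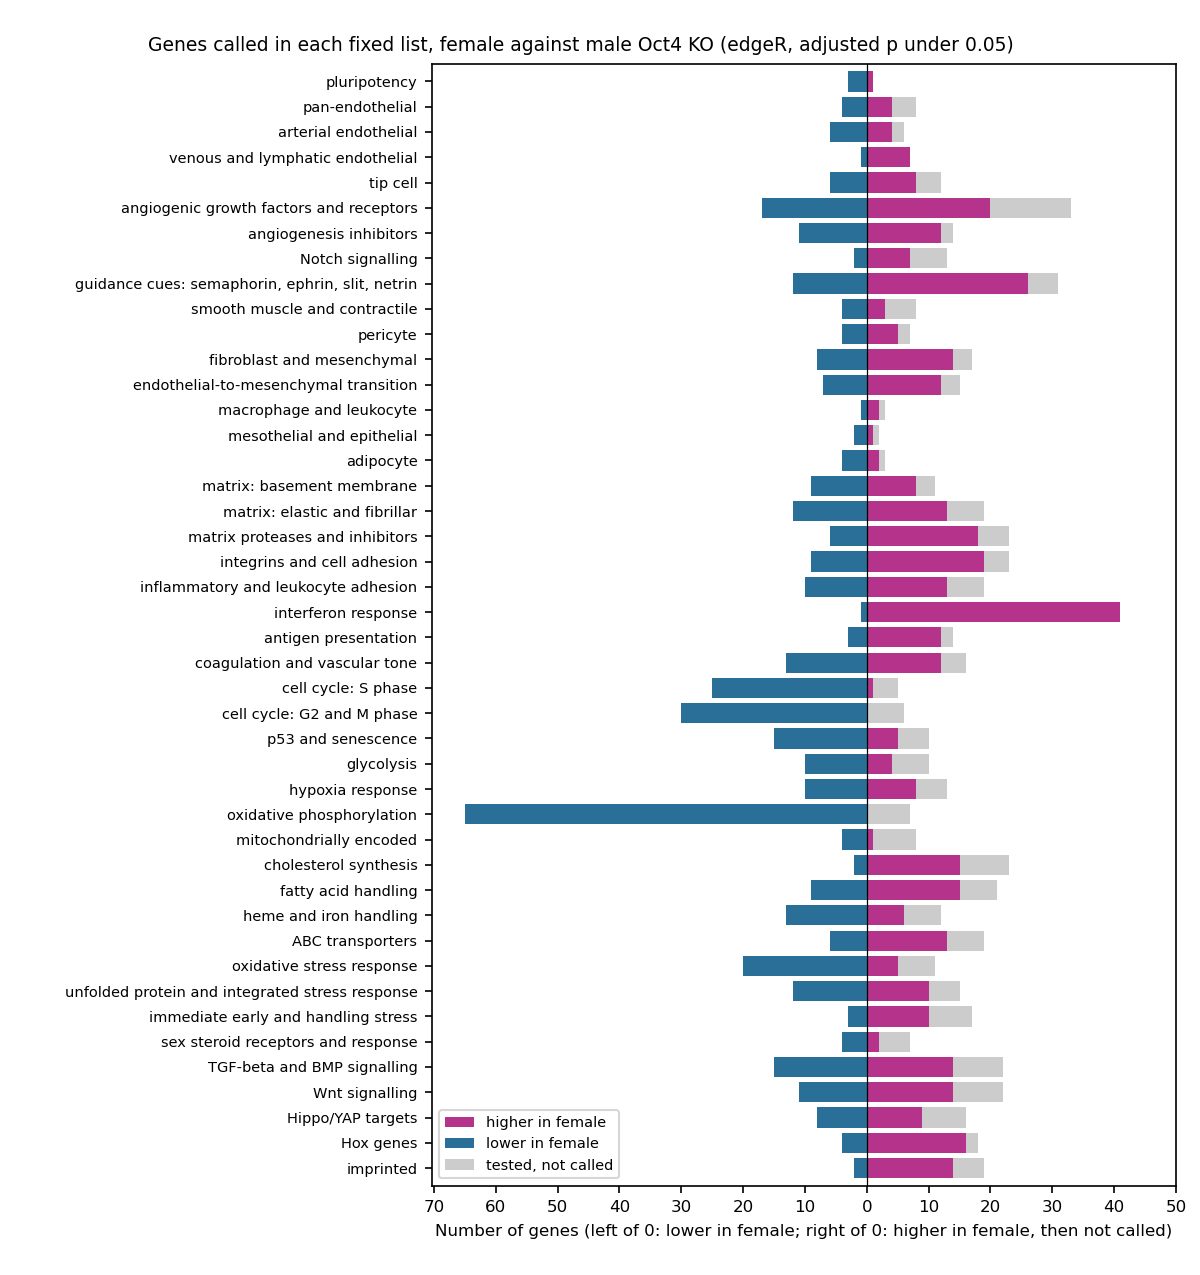
Number of tested genes of each fixed list that were lower in female cells (left of 0), higher in female cells or not called (right of 0), by edgeR at an adjusted p under 0.05. Interferon response genes lie almost wholly on the higher side (41 of 42) and oxidative phosphorylation genes on the lower side (65 of 72), while most lists divide.

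In all, 13 of the 41 lists were called with the preset correlation. Camera with an estimated correlation called none (lowest adjusted p = 0.056, with 8 lists at an unadjusted p under 0.05), and the directional test of fry called 34. The S phase, G2 and M phase, venous and lymphatic, and matrix protease lists had estimated correlations of -0.0123, -0.0119, -0.0263 and 0.000638, under the preset 0.01. Their camera p still rose, for S phase from 1.53e-06 to 0.00547 unadjusted. A larger correlation between the genes was therefore not why these lists lost their calls. Because sex was the only difference between the groups that the labels give, and each sex had 3 libraries, differences between the sexes and differences between these cultures for other reasons cannot be separated in these data.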

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

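The length and GC correction was chosen after the data had been seen, and the other alternatives before. The counts of called genes and of called lists stayed within 1.5 times their values under DESeq2, limma-voom, the other scalings and filters, robust dispersions, protein-coding genes only, the length and GC correction and each left-out library, with 2 exceptions. Testing for a minimum fold of 1.5 left 4053 genes, 2298 higher and 1755 lower in female cells, 3893 of them autosomal, because that test asks for a larger difference. The number of lists called was 0 with an estimated correlation and 34 with fry, which asks another question. Elsewhere the total ran from 8236 (without female replicate 1) to 9320 (no low-count filter), and with a library left out from 8236 to 8841 genes and 13 to 14 lists. DESeq2 called 8875 genes, 8824 of them shared. With the length and GC correction 8701 genes were called, 7358 of them shared with the 8993, and 7299 of those had the same sign. It made 4 lists pass with an estimated correlation, each at an adjusted p of 0.0493 (venous and lymphatic, matrix proteases, S phase and Hox genes). Of the genes the rule named and tested, 191 in all, only Myc changed direction while called in the main fit or in the alternative. It went from -0.20 to 0.02 with the length and GC correction, alone and with the replicate block, and the cause was not tested. Changes of direction in genes called in neither fit were not counted. Without the low-count filter 5 further lists were called (integrins, p53, cholesterol synthesis, immediate early and Hippo/YAP targets), none of which was called in the main fit with an estimated correlation (adjusted p = 0.373, 0.373, 0.299, 0.299 and 0.546). The larger side of the near-even angiogenic factor, hypoxia, Hippo/YAP and elastic matrix lists changed under at least 1 alternative. In all, 10 named genes lost their call with the minimum fold of 1.5, among them Kdm5c, Ddx3x and mt-Nd5.

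The replicate numbers do not pair the libraries. Deviations from the group means correlated at -0.016, -0.104 and -0.153 between libraries with the same number, and no library correlated best with its own number. With the replicate number as a replicate block 8525 genes were called, 4360 higher and 4165 lower, and 13 lists. Depth limits the genes at or under 3 counts, 0.123 to 0.154 CPM, where no difference between sexes was detectable if both lay there. The low-count filter also left some genes above that level untested, among them Kdr. Without the filter 25723 genes were tested rather than 14814.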

Other observations

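All tests in this part were chosen after the results had been seen. Homeobox transcription factors differed strongly more often than other genes. Of 73 tested genes that the deposited table assigns to the homeobox family, 16 (21.9%) were called and differed at least 8-fold, against 859 (5.8%) of all tested genes (two-sided Fisher's exact test, p = 3.31e-06, adjusted over 10 families 3.31e-05). Of the 16, 8 were Hox genes, whose differences had prompted the test. Without all Hox genes 8 of 51 (15.7%) differed by that much, against 851 of 14792 (5.8%) of all tested genes (same test, unadjusted p = 0.00818; genes are not independent). Isl1, Irx2, Hoxa6, Hoxb9 and the 5 tested HoxC genes were higher in female cells, and Alx1, Lhx9, Shox2, Msx1, Emx2, Irx1 and Hoxa10 were higher in male cells. Isl1, a transcription factor of cardiac and motor neuron progenitors, was at 15.5 ± 3.12 CPM in female cells with 0 counts in every male library (at least 111-fold higher). Zinc finger genes of the C2H2 family differed by that much less often than all tested genes, at 13 of 447 (2.9%, adjusted p = 0.0268 in the same exact test).

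The first pattern is the near absence of endothelial transcripts from cells described as endothelial. Shallow sequencing is argued against, since 3 counts make at most 0.154 CPM while fibroblast genes such as Col3a1 reached 3697 CPM in female and 2344 CPM in male cells. Mostly endothelial cultures that kept these genes and held some other cells are argued against by the pattern itself rather than by a separate test. The medians over the pan-endothelial list were 0.214 CPM in female and 0.184 in male cells, with 23 of 36 genes under 1 CPM in all libraries. Only 4 of the 36, Eng, Calcrl, Flt1 and Cd34, reached 10 CPM in every library. These values do not cover endothelial cells that had lost the expression of these genes. A loss of endothelial genes caused by the knockout stays open, with 0 wild-type libraries to compare with, as does growth or conversion of mesenchymal cells in culture, for which 18 of 26 genes of the fibroblast list fixed beforehand reached 10 CPM in all 6 libraries. These last explanations cannot be told apart here, because no cells of the wild-type genotype or earlier passage were analysed here.

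The second pattern is that most genes differed between the sexes, with HoxC and other positional genes absent or nearly absent from one sex. A direct effect of X and Y dosage limited to those chromosomes is argued against by the pattern itself rather than by a separate test, since 60.6% of autosomal genes were called. The length trend is argued against as the whole cause, since 7299 of the 8993 called genes kept their call and sign after it was removed. Whether the trend itself is technical (RNA quality or library preparation) or belongs to the cells was not tested. A candidate explanation is that the female and male cells arose from different positions along the body axis. All 5 tested HoxC genes were higher in female cells, but these genes are part of the pattern itself and no separate test. Among all 22 tested Hox genes 16 were higher and 4 lower in female cells. The labels do not give how many cultures or animals stood behind each sex, and the libraries divide only by sex. This explanation and an effect of sex therefore cannot be told apart. The sex of the animals stays an open explanation, untested.

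The third pattern is that genes of chromosome 10 were lower in female cells, with a median log2 fold change of -0.43 over its 536 tested genes with a mean of at least 5 CPM, the limit used for every chromosome and window here. The length and GC trend is argued against, since the median after correction was -0.47 (permutation p over genes 1e-04, the smallest the permutations can give, adjusted over 20 chromosomes 2e-04; genes are not independent). That test does not single out chromosome 10, since 13 of 20 chromosomes passed at an adjusted p under 0.05, 10 of them at the same smallest p; chromosome 10 had the lowest median of the 20 after correction, and the largest in size of either sign. A few strongly changed genes could not set a median over so many genes. The share of genes lower, 70.7% before and 77.4% after correction, therefore restates the pattern and is no separate test. Fewer copies of the chromosome per cell in the female cultures may account for it, since 7 of 7 windows of 20 Mb lay below the median window (-0.53 to -0.20). However, 8 of 20 chromosomes had every window on one side, and no DNA was measured, so copy number and regulation cannot be told apart; an effect of sex is untested.

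With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the other splits both groups held libraries of both sexes. The large difference between the sexes then counted as spread within the groups, which leaves few genes to call. The contrast with the real split therefore does not test chance. The real split called 8993 genes (4580 higher, 4413 lower, 8660 autosomal), and for each of these 4 counts it was the 1 split of 10 with as large a result, the highest of the other splits being 0 genes with edgeR, with DESeq2 and with limma-voom, and 41 to 91 at an unadjusted edgeR p under 0.05. For gene lists the real split called 13 and the highest other 7, so again 1 split of 10 gave as large a result.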
